A study of Homo sapiens with 9 samples.

How the data were processed

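MCF7 RNA samples were measured on 9 arrays: 3 of cells given 0.1% DMSO, 3 of cells given 1 µM MG132 for 4 h and 3 for 24 h. Per the labels' protocols, the cells were grown in MEM with serum, seeded overnight in phenol red-free medium with charcoal-stripped calf serum, then treated. RNA was isolated with the mirVana kit and labelled as Cy3 cRNA. Groups and replicate numbers were taken from the sample labels. Per the series' design text the samples of each time are independent experiments, so p-values measure the spread between such experiments, pooled over the 3 groups. The main fit does not pair samples. Its spread at 4 h therefore includes any state that same-numbered DMSO and 4 h samples share. The labels do not say when the DMSO cells were harvested.

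Each array's values are the processed signal intensity of Agilent Feature Extraction, version 9.5 per the submitters' processing notes and 9.5.3.1 per the file headers, in which the authors' software had subtracted background (a spatial detrending surface and negative controls). The arrays hold 45015 spots, of which 43376 are not controls, and these belong to 41000 probes. The authors' deposited value table of the whole series also holds intensity on a linear scale: each of its columns equalled the processed signal of its array at all 45015 spots within a relative tolerance of 1e-06, so it is neither centred nor on a log scale. Its column medians were 167, 132 and 127 for DMSO arrays 1 to 3, 142, 126 and 110 for the 4 h arrays, and 125, 123 and 135 for the 24 h arrays. Probe coordinates follow build hg17 (NCBI35), per the file headers; no genome or annotation of that build was used here. Gene names came from the files' accessions and symbols, matched without versions to a RefSeq gene table of GRCh38.p14 that was used only for names and for gene order. Of the 41000 probes 26829 matched (23434 by accession, 112 by another accession, 2317 by symbol and 966 by an older symbol), and 14171 kept the name in the file.

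Control spots were left out and spots marked as outliers (41 to 124 per array) were set to missing; no spot was saturated. Log2 of the processed signal was averaged over the spots of a probe, and the 75th percentile of each array's non-control spots was subtracted. Probes well above background on every array of at least 1 group were kept, which left 30198. Of a gene's probes with a value on at least 7 of the 9 arrays, the brightest on average stood for the gene. This gave 22655 genes, 14116 of them with a symbol from the gene table. The processed signal's 75th percentile was 1012 to 1522, its median 123 to 184, and 29413 to 32315 probes were well above background. The slope of the spike-in controls was 0.934 to 0.963, and the median CV between replicate spots 3.02% to 4.87%. Between arrays of a group the median absolute difference was 0.18 to 0.43 on the log2 scale, so no arrays appeared to be copies. Background subtraction and dim signals limit the size of a change: where a probe was not well above background on any array of a group, the change is given as at least N-fold. That bound is the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, as means of normalized log2 values.

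Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with all 9 arrays in 1 fit, no covariate, Benjamini-Hochberg adjustment over all genes, and an adjusted p threshold of 0.05. The median SE was 0.24 on the log2 scale. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with the correlation estimated from the arrays; a list's median, mean and camera direction had the same sign in every called list. The lists were 26S proteasome subunits, immunoproteasome and antigen presentation, cytosolic heat shock response, integrated stress response, endoplasmic reticulum chaperones and degradation, NRF2 targets, metallothioneins, AP-1 and immediate early genes, ubiquitin and autophagy, estrogen receptor alpha targets, luminal epithelial identity, G1/S and DNA replication, G2/M and mitosis, p53 targets, NF-kappaB targets, pro-apoptotic genes, anti-apoptotic genes, cholesterol biosynthesis, RNA polymerase II subunits and elongation, H3K4 methyltransferase complexes, histones, ribosomal proteins, and markers of fibroblasts, leukocytes and basal epithelium. Besides methyltransferase complex genes, the H3K4 list holds the demethylase genes KDM5A, KDM5B, KDM5C and KDM1A. Setting members that were below background throughout a group at their bound left every list's median the same.

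Named genes follow a rule. For each time against DMSO it takes the 6 largest rises and 6 largest falls among genes with a symbol that passed the test, were well above background on all 9 arrays without outlier spots and separated the groups completely, the 3 members of each list with the largest change past the test, and a fixed panel (HSPA1A, DNAJB1, BAG3, HMOX1, DDIT3, ATF3, SQSTM1, PSMD12, PSMB5, ESR1, PGR, GREB1, TFF1, CCND1, MYC, CDKN1A and MKI67). Between the times it takes the 5 largest rises and 5 largest falls within the same limits, and the panel. The text leaves out some members with the smallest changes within a list, and adds members of small counts that the text marks as chosen after their values were seen. Genes with near-identical copies (HSPA1A and HSPA1B, MT1 genes, HLA genes, histones, GABARAPL1) are given as the probe's signal.

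Arrays lay on 3 slides, and each slide was a scan of its own: slide 1 held DMSO array 1, slide 2 held DMSO array 2, 4 h arrays 1 and 3 and 24 h array 2, and slide 3 held DMSO array 3, 4 h array 2 and 24 h arrays 1 and 3. Slide was fitted as a fixed and as a random block and within slides 2 and 3. The fixed block takes DMSO array 1, alone on slide 1, out of every contrast. It thus tests slide and the loss of that array together. In the random block, arrays of a slide had a consensus correlation of -0.153. Whether replicate numbers pair the samples was checked by correlating, across genes, deviations from the group means, before the calls of the fits were compared. Between DMSO and 4 h arrays the same-numbered pairs gave 0.345, 0.241 and 0.243, with 0.0654 as the highest of the other pairs, so these numbers pair the samples by the threshold of 0.1. The pairing comes from the data, since the labels state no shared day. The other group pairs did not pass this check. Alternatives tried were normexp (offset 50) on mean and background signals, quantile, median and no scaling, no filter or a filter on all 9 arrays, every probe on its own, the replicate block, the slide settings, only the groups compared, eBayes with trend and robust, array weights, the authors' value table, stricter thresholds, and leaving out each array. A difference of 1.5 times in a count was taken as a change.

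The gene step was tested on simulated data on 22655 genes, with 200 of them changed, 50 at each of 4 log2 sizes. Of genes changed by 0.5, 1, 2 and 4, limma called 0%, 48%, 78% and 96% for 4 h against DMSO, where 10 of 121 calls were of unchanged genes. For 24 h against DMSO it called 2%, 30%, 86% and 100%, with 7 of 116 calls unchanged, and between the times 0%, 36%, 82% and 96%, with 7 of 114. A simulated list of 30 genes shifted by 0.5 was called in all 3 comparisons, and camera called 0 of 20 unshifted lists. In the real comparisons 788, 9613 and 6090 genes passed, and the size of p that passes the adjustment depends on that number. The simulated percentages therefore do not give the sensitivity of the real tests. The simulated genes were drawn independently of each other. This does not test list calls under correlation between genes, which was estimated at 0.38 for proteasome subunits and 0.88 for G2/M genes.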

Results

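Transcript levels were measured in MCF7 cells, an established estrogen receptor positive human breast cancer line, after inhibition of the proteasome, the complex that degrades ubiquitin-tagged proteins. The cells received 1 µM MG132, a peptide aldehyde that blocks the proteasome's active sites, for 4 h or 24 h, or 0.1% DMSO as vehicle. The 9 samples form 3 groups of 3, which the series' design text describes as independent experiments, and each sample was hybridised to its own 1-colour Agilent whole genome array. The question the series states is how the inhibitor alters mRNA levels at these times. The labels give the DMSO samples no time of their own, so both times were compared with the same 3 DMSO arrays, and longer culture was not separated from longer exposure to MG132. Across the arrays the 75th percentile of signal ran from 1012 to 1522 units, and 71.7% to 78.8% of the 41000 probes were well above background. The number of arrays limits the precision of every change given here.

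Arrays of a group resembled each other more than arrays treated for 24 h resembled DMSO arrays. Pearson's r over the tested genes (genes are not independent replicates) was 0.986 to 0.993 among DMSO arrays, 0.981 to 0.990 among 4 h arrays and 0.972 to 0.985 among 24 h arrays. It was 0.972 to 0.983 between DMSO and 4 h arrays, 0.914 to 0.934 between DMSO and 24 h arrays, and 0.940 to 0.960 between 4 h and 24 h arrays. The first principal component held 63.3% of the variance and the second 10.5%. Of 22655 genes tested, 788 differed from DMSO at 4 h, 9613 differed at 24 h, and 6090 differed between the times (limma, Benjamini-Hochberg adjusted p under 0.05). In what follows, changes are log2 values ± SE from limma with 3 arrays per group, and p-values of genes are adjusted by the Benjamini-Hochberg method over all genes tested.

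After 4 h of MG132, genes of protein quality control and of several stress responses rose. The lists were called at camera's preset correlation; with an estimated correlation camera called 0 of 25, with 6 at an unadjusted p under 0.05. HSPA6, a strictly stress-inducible HSP70 chaperone, rose by 5.08 ± 0.93 (33.9-fold, adjusted p = 0.0214). STYK1, a receptor-like kinase, rose by 4.47 ± 0.20 (adjusted p = 4.78e-05). SLC7A11, the cystine transporter subunit, rose by 4.08 ± 0.50. OSGIN1, an oxidative stress gene, the deubiquitinase gene UCHL1 and the ganglioside synthase gene B4GALNT1 rose by 3.94 ± 0.21, 3.86 ± 0.21 and 3.56 ± 0.22. Among genes with a symbol that were well above background on all 9 arrays, the largest falls were those of the noncoding RNA LINC00052 (-1.90 ± 0.35, adjusted p = 0.0214), of WEE1, a kinase that restrains entry into mitosis (-1.88 ± 0.27), and of the chromatin-associated ARID5B (-1.87 ± 0.27). Those of IGDCC3 (-1.77 ± 0.29), BAHCC1 (-1.74 ± 0.18) and ACSS1 (-1.70 ± 0.36) followed. The probe of HSPA6 lies at chromosome 1, 158309213 to 158309272, that of STYK1 at chromosome 12, 10663121 to 10663180, and that of LINC00052 at chromosome 15, 85923671 to 85923730, in the coordinates of human build hg17. Whether they lie in an exon's coding part or a UTR was not determined.

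In all, 560 genes were higher and 228 lower at 4 h, which is 3.48% of the genes tested. Of these, 574 differed by at least 2-fold (419 higher, 155 lower). The count at 4 h depended on single arrays: it was 160, 184 and 361 without DMSO array 1, 2 or 3. It was 179 without 4 h array 1, 232 without 4 h array 2, and 1342 without 24 h array 3, which enters only the shared estimate of the spread. It was 861 with the replicate number as a block, 2210 (1150 higher, 1060 lower) with that block and only the DMSO and 4 h arrays, 1500 with those 6 arrays and no block, and 4046 (2109 higher, 1937 lower) with array weights, so the share of higher genes, 71.1% here, fell to 52.0% and 52.1% in these 2 settings. With slide as a fixed block it was 70, and within slide 2, with 1 DMSO array against 2, it was 634. Within slide 3, with 1 array against 1, limma called 0 genes, with 855 at an unadjusted p under 0.05. Without scaling between arrays 409 genes passed, without the filter on dim probes 435, and at an adjusted p under 0.01 177. Of the 40 genes named here that passed at 4 h, the calls of 18 were kept whichever array was left out. These were ARID5B, B4GALNT1, BAHCC1, CDKN1A, FAS, GABARAPL1, HMOX1, HSPA1A, HSPH1, MAFG, OSGIN1, PSMC6, PSMD12, SLC7A11, STYK1, TNFRSF10B, UBQLN1 and UCHL1. Leaving out DMSO array 1, 2 or 3 ended 21, 19 and 8 of the 40 calls (adjusted p 0.0516 to 0.203, 0.0627 to 0.178 and 0.0531 to 0.128). Leaving out 4 h array 1, 2 or 3 ended 20, 17 and 9 (up to 0.161, 0.149 and 0.0992). Without 24 h array 1 the call of PSMB5 ended (adjusted p = 0.0538), and without 24 h array 2 those of HSPA4L, FEN1 and VIM (0.0519 to 0.0592). HSPA6 was among the calls lost, with adjusted p = 0.0761, 0.0939 and 0.0688 without DMSO array 1, 2 or 3 and 0.0979 and 0.0787 without 4 h array 1 or 2. Slide as a fixed block ended 28 of these 40 calls, with no change of direction. That block also takes out DMSO array 1, the loss of which by itself ended 21 of them.

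All 25 gene lists tested had been fixed before the data were examined, as had the rule for named genes, the filter and the tests. Subunits of the 26S proteasome rose at 15 of 33 members, or 27 adjusted over the list alone (median 0.80, camera adjusted p = 1.53e-22, estimated-correlation adjusted p = 0.138). Among them PSMD12 rose by 1.48 ± 0.18, PSMD1 by 1.46, PSMC6 by 1.43 and PSMB5, a catalytic subunit, by 0.80 ± 0.18 (adjusted p = 0.044). Cytosolic heat shock genes rose at 11 of 27 members (24 adjusted over the list alone; median 1.31, camera adjusted p = 9.4e-19, estimated-correlation adjusted p = 0.199). HSPA4L and HSPH1, chaperones of the HSP110 family, rose by 2.76 ± 0.59 and 2.57 ± 0.30, HSPA1A by 2.27 and its cochaperone gene DNAJB1 by 2.16. BAG3 had a change of 1.12 ± 0.41 and did not pass (adjusted p = 0.192). Sequence shared with HSPA1B keeps the HSPA1A probe from being read as that gene alone. In the integrated stress response list, targets of the transcription factors ATF4 and CHOP, 15 of 27 members rose (21 adjusted over the list alone; median 1.54, camera adjusted p = 1.2e-18, estimated-correlation adjusted p = 0.138). These included PSAT1 of serine synthesis (2.91 ± 0.50), DDIT3, which encodes CHOP (2.21 ± 0.32), ATF3 (2.01 ± 0.43) and ADM2 (2.85 ± 0.51), the last of them well above background on 1 of the 3 DMSO arrays. Of NRF2 targets, genes of the oxidative stress response, 9 of 24 rose (12 adjusted over the list alone; median 0.62, camera adjusted p = 6.51e-12, estimated-correlation adjusted p = 0.138). The heme oxygenase gene HMOX1 rose by 2.87 ± 0.37. SLC7A11 belongs to this list and to the previous one.

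Targets of p53 rose at 16 of 28 members, 20 higher and 1 lower adjusted over the list alone (median 1.15, camera adjusted p = 5.13e-17, estimated-correlation adjusted p = 0.139). Among them were the death receptor gene FAS (3.12 ± 0.35), GADD45A (2.58 ± 0.43) and the cell cycle inhibitor gene CDKN1A (2.34 ± 0.23). In the list of pro-apoptotic BCL2 family members and death receptors 4 of 13 rose, 4 higher and 2 lower adjusted over the list alone (median 0.36, camera adjusted p = 0.0179, estimated-correlation adjusted p = 0.139). They were FAS, PMAIP1, which encodes NOXA (2.57 ± 0.43), TNFRSF10B (1.94 ± 0.23) and TNFRSF10A (1.92 ± 0.27). Its call was lost with the replicate block and only DMSO and 4 h arrays (camera adjusted p = 0.0741), and its median was 0.14 without 4 h array 3. Ubiquitin and autophagy genes rose at 5 of 25 members, 11 higher and 1 lower adjusted over the list alone (median 0.50, camera adjusted p = 1.14e-07, estimated-correlation adjusted p = 0.138). These were UCHL1, the autophagosome gene GABARAPL1 (2.79 ± 0.31), UBQLN1 (1.64 ± 0.17), the autophagy receptor gene SQSTM1 (1.54 ± 0.25) and NPLOC4 (1.29 ± 0.16). AP-1 and immediate early genes had 3 of 23 members higher (4 adjusted over the list alone; median 0.29, camera adjusted p = 0.00738, estimated-correlation adjusted p = 0.302), namely FOSL1 (2.07 ± 0.37), MAFG (1.41 ± 0.15) and IER5 (1.04 ± 0.22). The AP-1 median was 0.54 without 4 h array 1. NPLOC4 and TNFRSF10A fall outside the rule for named genes at 4 h and were chosen after their values were seen. With the replicate block the calls of ATF3, ESR1 and PSMB5 at 4 h ended (adjusted p = 0.0532, 0.0598 and 0.0621). With only DMSO and 4 h arrays in that fit, those of ATF3 and FOSL1 ended (0.061 and 0.0524) and CCND1 and MKI67 passed as lower (0.0285 and 0.0206).

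Lists that were lower at 4 h shifted with few single genes past the test. The luminal epithelial list was lower (median -0.46, camera adjusted p = 0.000201, estimated-correlation adjusted p = 0.302). ESR1, the estrogen receptor alpha gene, fell (-0.94 ± 0.20, adjusted p = 0.0402) as the only member of 21 past the test, with 2 adjusted over the list alone. Genes of G1/S and DNA replication were lower (median -0.60, camera adjusted p = 3.76e-07, estimated-correlation adjusted p = 0.518). FEN1 fell (-1.30 ± 0.30), and 3 of 39 members passed adjusted over the list alone. Genes of G2/M and mitosis were lower as a list (median -0.82, camera adjusted p = 5.45e-05, estimated-correlation adjusted p = 0.714). No member passed limma's adjusted test, and 1 of 34 was lower at an unadjusted p under 0.05. MKI67 had a change of -1.21 ± 0.65 (adjusted p = 0.37). The G2/M call was lost without 4 h array 3 (median -0.34, camera adjusted p = 0.243), and its median was -0.44 and -1.43 without DMSO array 2 or 3. That of G1/S was -0.39 without DMSO array 2 and -0.34 without 4 h array 3, and that of the luminal list -0.29 without 4 h array 1. Histone genes were lower (median -0.40, camera adjusted p = 0.00209, estimated-correlation adjusted p = 0.534) with no member past limma's adjusted test and 2 of 19 at an unadjusted p under 0.05. Within a slide DMSO is 1 array, so medians by slide rest on single arrays. On slide 2, on slide 3 and with slide as a block, the 4 h medians of the lists were 0.65, 0.90 and 0.72 for proteasome subunits, 1.01, 1.77 and 1.28 for heat shock genes, 1.96, 1.23 and 1.31 for the integrated stress response, and 0.60, 0.53 and 0.51 for NRF2 targets. They were 1.10, 1.20 and 1.13 for p53 targets, 0.31, 0.20 and 0.27 for pro-apoptotic genes, 0.52, 0.39 and 0.50 for ubiquitin and autophagy genes and 0.41, 0.26 and 0.26 for AP-1 genes. The luminal list had -0.41, -0.51 and -0.44 and the histone list -0.41, -0.39 and -0.35. The cell cycle lists changed sign between the slides, at -1.17, 0.31 and -0.51 for G1/S and -1.90, 1.05 and -0.65 for G2/M. Within the replicate numbers 1, 2 and 3, the mean G2/M change from DMSO to 4 h was -0.98, -0.88 and -0.62. Of the 12 lists called at 4 h, 10 had the same sign on both slides.

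The other 13 lists did not pass at 4 h. NF-kappaB targets had a median of 0.094 (camera adjusted p = 0.336), with NFKBIE, an inhibitor of that factor, higher (0.88 ± 0.18). Fibroblast markers had a median of -0.27 (0.115), with VIM lower (-0.86 ± 0.19). The median was -0.075 for estrogen receptor alpha targets (camera adjusted p = 0.659). None of the fixed panel's members PGR (-0.36 ± 0.39, adjusted p = 0.685), GREB1 (-0.52 ± 0.43, 0.579), TFF1 (-0.060 ± 0.21, 0.917) and CCND1 (-0.98 ± 0.24, 0.0584) passed. MYC had a change of 0.19 ± 0.31 (adjusted p = 0.792). Endoplasmic reticulum chaperones had a median of 0.10 (camera adjusted p = 0.659), metallothioneins -0.33 (0.0645), immunoproteasome and antigen presentation genes -0.037 (0.941) and ribosomal proteins 0.11 (0.121). The medians of anti-apoptotic genes, cholesterol biosynthesis, RNA polymerase II subunits and H3K4 methyltransferase complexes were 0.093, -0.10, -0.071 and -0.018 (camera adjusted p = 0.797, 0.659, 0.659 and 0.766). Those of leukocyte and basal epithelial markers were 0.30 and 0.14 (0.0992 and 0.815). Some of these medians turned sign under another scaling: endoplasmic reticulum, NF-kappaB and anti-apoptotic lists (-0.030, -0.032 and -0.033) and ribosomal proteins (-0.021) with no scaling, ribosomal proteins (-0.010) with quantile scaling, and H3K4 complexes (0.0090) with median scaling. Leaving out 1 array brought some of these lists past the test, such as metallothioneins without DMSO array 1 or 3 (0.0172 and 0.0142) or 4 h array 2 or 3 (0.0452 and 0.0110). The others were leukocyte markers without DMSO array 3 (0.00962) or 4 h array 1 (0.0380), and ribosomal proteins without DMSO array 3 (0.0298) or 4 h array 1 or 2 (0.0169 and 0.00862).

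**Figure D1:**
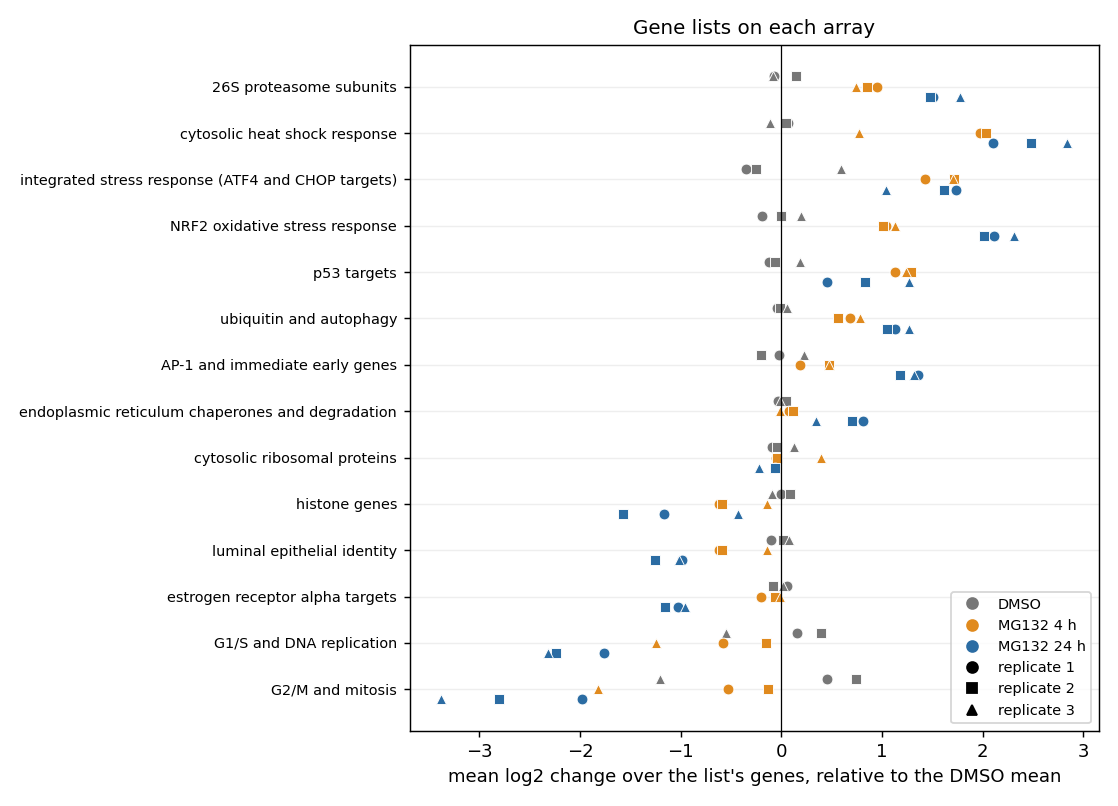
Mean log2 change relative to the DMSO mean over the tested genes of 14 gene lists on each of the 9 arrays; colours mark the groups and symbols the replicate numbers. Proteasome subunits lay at 0.74 to 0.95 on the 4 h arrays and 1.47 to 1.78 on the 24 h arrays, and G2/M genes spread from -1.20 to 0.75 among the DMSO arrays alone.

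After 24 h of MG132 the same stress lists were higher, and the estrogen receptor, luminal and cell cycle programs were lower than in DMSO, by camera at its preset correlation. With an estimated correlation, camera called 0 of 25 lists, with 5 at an unadjusted p under 0.05. The order of the next 12 genes holds among those with a symbol that were well above background on all 9 arrays. MLLT11 had the largest rise, 7.44 ± 0.32 (173-fold, adjusted p = 1.94e-06). Next came the chemokine gene CCL26 (7.22 ± 0.66), STYK1 (6.44 ± 0.20), GABARAPL1 (6.40 ± 0.31), EPDR1 (6.28 ± 0.22) and DUSP13A (6.16 ± 0.31). IGFBP5, which encodes a binding protein of insulin-like growth factors, had the largest fall (-6.44 ± 0.57). Next came AFAP1L2 (-6.09 ± 0.45), FGD3 (-5.68 ± 0.68), the transcription factor genes MYB (-5.68 ± 0.25) and E2F2 (-5.66 ± 0.75), and SCUBE2 (-5.58 ± 0.28). ESR1 fell by 4.62 ± 0.20 on the log2 scale, a 24.6-fold difference (adjusted p = 1.97e-06). In hg17 coordinates, the probes of MLLT11, IGFBP5 and ESR1 lie at chromosome 1, 147853831 to 147853890, chromosome 2, 217362673 to 217362732 and chromosome 6, 152516022 to 152516081. The GABARAPL1 probe shares sequence with the related GABARAPL3, so its signal cannot be given to a single copy.

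At 24 h, 4523 genes were higher and 5090 lower, together 42.4% of the genes tested. Of these, 6142 differed by at least 2-fold (2591 higher, 3551 lower). With slide as a fixed block 6906 genes passed. Within slide 2, with 1 array against 1 and the spread taken from the 4 h arrays alone, 4980 passed. Within slide 3, with 1 DMSO array against 2, limma called 0, with 4318 at an unadjusted p under 0.05. Median scaling in place of the 75th percentile moved the median change of all genes to 0.14, and the split to 5507 higher and 4355 lower, 55.8% higher against 47.1%. Which direction prevailed at 24 h thus depended on the scaling. Under the other scalings, none of the 25 lists or of the genes named at 24 h turned its sign where it was called, but medians of lists that did not pass did. That of ribosomal proteins went from -0.11 to 0.020 with median scaling, and that of cholesterol biosynthesis from 0.018 to -0.11 with quantile scaling. Of the 90 genes named at 24 h that passed, 85 kept their call whichever array was left out. CSF1R lost it without DMSO array 1 (adjusted p = 0.0794) or 24 h array 3 (0.0539), and CTR9 without DMSO array 2 (0.0512). KMT2E lost it without DMSO array 2 or 3 (0.063 and 0.0865) or 24 h array 1 or 2 (0.0639 and 0.0612), and MT2A without DMSO array 2 (0.124) or 24 h array 2 or 3 (0.0974 and 0.0816). MT1G lost it without any of the DMSO or 24 h arrays or 4 h array 2 (0.0560 to 0.181).

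All 33 proteasome subunits rose at 24 h (median 1.67, camera adjusted p = 2.15e-16, estimated-correlation adjusted p = 0.179). PSMC4 rose by 2.75 ± 0.20, PSMD12 by 2.31 ± 0.18, PSMD14 by 2.21 ± 0.16 and PSMB5 by 1.40 ± 0.18. Heat shock genes rose at 26 of 27 members (median 2.38, camera adjusted p = 1.18e-11, estimated-correlation adjusted p = 0.341). They included HSPA6 (6.09 ± 0.93), HSPB8 (4.99 ± 0.46), ZFAND2A (4.11 ± 0.46), DNAJB1 (3.17 ± 0.36), HSPA1A (2.54 ± 0.27) and BAG3 (2.38 ± 0.41). NRF2 targets rose at 19 of 24 (20 adjusted over the list alone; median 1.76, camera adjusted p = 3.1e-11, estimated-correlation adjusted p = 0.137). SLC7A11 rose by 5.42 ± 0.50, OSGIN1 by 5.28 ± 0.21 and HMOX1 by 4.39 ± 0.37. Integrated stress response genes rose at 15 of 27 (16 adjusted over the list alone; median 1.25, camera adjusted p = 1.13e-05, estimated-correlation adjusted p = 0.341). ATF3 rose by 4.14 ± 0.43, CTH by 3.07 ± 0.20 and DDIT3 by 2.74 ± 0.32. Endoplasmic reticulum chaperones and degradation genes, which did not pass at 4 h, rose at 15 of 25 (median 0.64, camera adjusted p = 0.000434, estimated-correlation adjusted p = 0.341). HYOU1 rose by 2.06 ± 0.22, while the transcription factor gene XBP1 fell (-1.08 ± 0.38). AP-1 and immediate early genes rose at 12 of 23 (13 adjusted over the list alone; median 0.89, camera adjusted p = 2.14e-05, estimated-correlation adjusted p = 0.179). FOSL1 rose by 5.40 ± 0.37, MAFF by 4.51 ± 0.31 and MYC by 1.29 ± 0.31, for which 1 of the 2 other probes had the opposite sign. Ubiquitin and autophagy genes rose at 16 of 25 (17 adjusted over the list alone; median 0.79, camera adjusted p = 1.72e-05, estimated-correlation adjusted p = 0.179). Among them were UCHL1 (4.38 ± 0.21) and SQSTM1 (2.78 ± 0.25), and 2 fell, GABARAP (-0.97) and NBR1 (-1.20). On slide 2, on slide 3 and with slide as a block, the 24 h medians were 1.28, 1.83 and 1.59 for proteasome subunits, 2.14, 2.51 and 2.36 for heat shock genes. They were 1.40, 1.95 and 1.71 for NRF2 targets and 1.67, 0.56 and 0.93 for the integrated stress response. The others were 0.73, 0.69 and 0.64 for endoplasmic reticulum genes, 1.03, 0.84 and 0.80 for AP-1 genes and 0.71, 0.83 and 0.72 for ubiquitin and autophagy genes.

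Estrogen receptor alpha targets were lower at 24 h, with 16 of 27 falling and 3 rising (median -1.05, camera adjusted p = 0.000846, estimated-correlation adjusted p = 0.137). TFF3 fell (-4.53 ± 0.52), as did GREB1 (-3.74 ± 0.43), CCND1 (-2.07 ± 0.24) and TFF1 (-1.05 ± 0.21). By contrast, the growth factor gene AREG (4.12 ± 0.39), the cathepsin gene CTSD (1.30) and the cochaperone gene FKBP4 (0.95) rose. PGR, the progesterone receptor gene, had a change of 0.14 ± 0.39 (adjusted p = 0.808). Luminal genes fell at 12 of 21 members (13 adjusted over the list alone; median -0.66, camera adjusted p = 0.00661, estimated-correlation adjusted p = 0.401). ESR1, SPDEF (-4.11 ± 0.32) and MUC1 (-3.83 ± 0.41) led, and FOXA1 (0.67), AR (0.78) and CLDN4 (1.76) rose. Genes of G1/S and DNA replication fell at 30 of 39 (33 adjusted over the list alone; median -2.01, camera adjusted p = 2.29e-10, estimated-correlation adjusted p = 0.341). UHRF1 fell by 6.05 ± 0.82, with 2 of 3 treated arrays well above background, as did E2F2 and TK1 (-4.84 ± 0.71). Genes of G2/M and mitosis fell at 29 of 34 (32 adjusted over the list alone; median -2.90, camera adjusted p = 1.64e-08, estimated-correlation adjusted p = 0.401). These included TOP2A (-4.90 ± 0.87), AURKB (-4.43 ± 0.95, above background on 1 of 3 treated arrays) and the proliferation marker gene MKI67 (-3.21 ± 0.65). Histone genes fell at 10 of 19 (median -1.06, camera adjusted p = 0.00156, estimated-correlation adjusted p = 0.401). H2BC5 fell by 2.17 ± 0.29, with related copies that its probe cannot be assumed to tell apart. The medians on slide 2, on slide 3 and with slide as a block were -1.29, -1.11 and -1.17 for receptor targets, -0.68, -0.55 and -0.54 for luminal genes. They were -2.27, -1.55 and -1.93 for G1/S, -3.61, -1.72 and -2.65 for G2/M and -1.78, -0.77 and -1.14 for histones.

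Targets of p53 rose at 12 of 28 members and fell at 2 (median 0.69, camera adjusted p = 0.00487, estimated-correlation adjusted p = 0.458). GADD45A rose by 3.55 ± 0.43, PLK3 by 2.89 ± 0.22, FAS by 2.81 ± 0.35 and CDKN1A by 2.30 ± 0.23, and TP53INP1 (-0.81) and PLK2 (-0.95) fell. NF-kappaB targets rose at 9 of 20 (median 0.33, camera adjusted p = 0.0148, estimated-correlation adjusted p = 0.401), and LTB fell (-1.31). The chemokine gene CXCL8, not well above background on any DMSO array, was at least 3.7-fold higher (adjusted p = 2.08e-06), IL6 rose by 3.74 ± 0.47 with 2 of 3 DMSO arrays above background, and RELB rose by 2.54 ± 0.42. The NF-kappaB call was lost with probes required above background on all 9 arrays (camera adjusted p = 0.109) and without 24 h array 1 (0.0555). Its median was 0.17, 0.17 and 0.80 without DMSO array 1, 2 or 3, and 0.58 and 0.22 without 24 h array 2 or 3, while that of p53 targets was 0.31 without 24 h array 3. Metallothioneins were lower (median -0.74, camera adjusted p = 0.00906, estimated-correlation adjusted p = 0.458). MT1F (-2.28 ± 0.26), MT2A (-1.05 ± 0.34), MT1G (-0.81), MT1L (-0.80) and MT1H (-0.74) fell of 9 tested, and 8 adjusted over the list alone. These copies share sequence. Their medians on slide 2, on slide 3 and with slide as a block were 0.46, 0.65 and 0.59 for p53 targets, 0.33, 0.29 and 0.14 for NF-kappaB targets and -1.30, -0.56 and -0.81 for metallothioneins. Apart from MT1G, which the rule names, members given in the 24 h results with a value but no SE fall outside the rule for named genes, as does XBP1. Those outside it were chosen after their values were seen. All 15 lists called at 24 h had the same sign on both slides.

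The other 10 lists did not pass as lists at 24 h, although single members changed. Among pro-apoptotic genes (median 0.34, camera adjusted p = 0.104), 5 of 13 rose, namely TNFRSF10A (3.19 ± 0.27), PMAIP1 (3.16 ± 0.43), FAS, TNFRSF10B (2.10) and BID (1.16). BMF (-4.78 ± 0.40) and BIK (-1.12) fell. Of anti-apoptotic genes (median 0.21, 0.542), BIRC5, also a mitotic gene, fell (-3.40 ± 0.69), as did BCL2A1 (-0.69), and MCL1 (0.93 ± 0.15) and CFLAR (0.94 ± 0.23) rose. Immunoproteasome and antigen presentation genes went both ways (median 0.29, 0.397). HLA-A was among 6 that rose, by 2.45 ± 0.25 with sequence close to other HLA genes. PSME1 (-1.43), TAPBP (-1.31), PSMB10 (-0.89), PSME2 (-0.81) and PSMB8 (-0.61) fell. In cholesterol biosynthesis (median 0.018, 0.896), LDLR (1.11 ± 0.20), MVD (0.89), HMGCR (0.77) and STARD4 (0.67) rose, and TM7SF2 (-2.75 ± 0.42), LSS (-1.17 ± 0.19) and DHCR24 (-0.75) fell. RNA polymerase II and elongation genes had a median of 0.21 (0.137), with POLR2C (1.33 ± 0.18), SUPT6H (1.18 ± 0.21), CTR9 (0.62 ± 0.16), SUPT5H (0.59) and CDK9 (0.43) higher and POLR2H (-0.61) lower. The H3K4 methyltransferase list, which also holds demethylase genes, had a median of 0.11 (0.43). SETD7 (0.86 ± 0.16), WDR5 (0.59) and the demethylase gene KDM5C (0.79 ± 0.19) were higher and KMT2E (-0.66 ± 0.20) lower. Ribosomal protein genes had a median of -0.11 (0.382), and none of 46 passed limma's adjusted test, with 1 lower at an unadjusted p under 0.05.

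Among markers of other cell types, fibroblast genes had a median of -0.74 (camera adjusted p = 0.0751), with VIM at least 6.08-fold lower, below background on the 24 h arrays (adjusted p = 1.18e-05). COL5A1 (-2.28 ± 0.36), S100A4 (-1.72 ± 0.24) and COL3A1 (-1.10, above background on 2 of 3 treated arrays) fell. Leukocyte genes had a median of 0.53 (0.116, or 0.0381 without DMSO array 3), with the lysosomal marker gene CD68 (2.45 ± 0.24) and CSF1R (0.84 ± 0.24) higher. Basal epithelial markers had a median of 1.41 (0.0974). LAMC2 (5.09 ± 0.27), ITGA6 (2.99 ± 0.30), EGFR (2.34) and ACTA2 (1.33) rose, and CAV1 (-2.39 ± 0.54) and CDH3 (-0.83) fell.

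**Figure D2:**
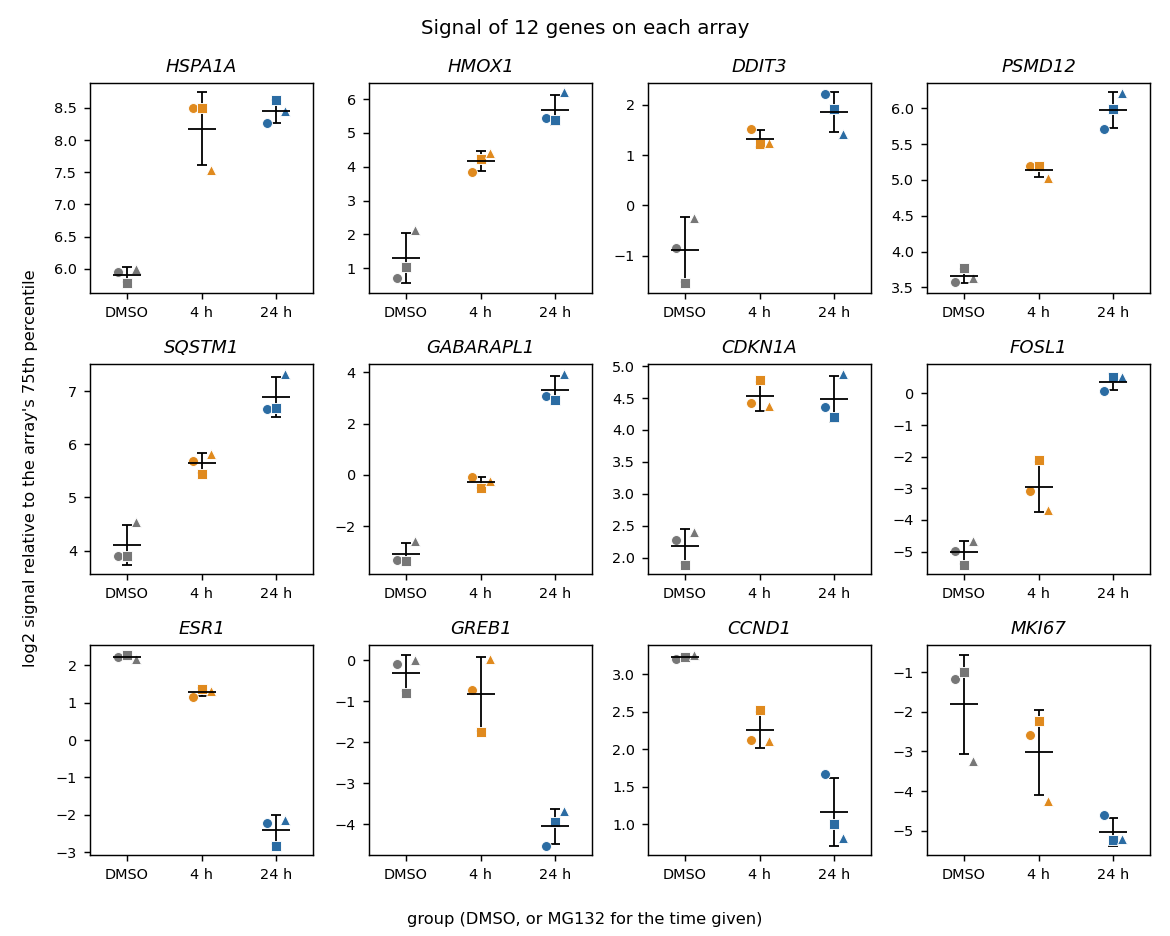
Log2 signal of 12 genes relative to each array's 75th percentile on the 9 arrays (symbols, by replicate number), with the group mean and SD (bar and whiskers, 3 arrays). ESR1 lay lower at 24 h than in DMSO on every array, with a change of -4.62, while HMOX1 and FOSL1 lay higher by 4.39 and 5.40.

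Between the times, estrogen receptor targets and cell cycle genes were lower at 24 h than at 4 h, while the heat shock gene HSPA1A, DDIT3 and CDKN1A did not pass the test of the difference. With an estimated correlation these lists did not pass (adjusted p = 0.110 for receptor targets, 0.474 for G1/S and 0.560 for G2/M). Among genes with a symbol that were well above background on all 9 arrays, MMP1, a collagenase gene, was 6.01 ± 0.73 higher at 24 h than at 4 h, and MLLT11 (5.81 ± 0.32), NIBAN1 (5.13 ± 0.58), LAMC2 (4.70 ± 0.27) and the protease-activated receptor gene F2RL1 (4.31 ± 0.51) followed. The largest falls from 4 h to 24 h by the same limit were those of IGFBP5 (-5.46 ± 0.57), MYB (-5.29 ± 0.25), SCUBE2 (-5.03 ± 0.28), the replication factor gene PCLAF (-4.69 ± 0.46) and ELAPOR1 (-4.54 ± 0.45). ESR1 was lower at 24 h than at 4 h (-3.68 ± 0.20, adjusted p = 1.46e-05), as were GREB1 (-3.22 ± 0.43), CCND1 (-1.09 ± 0.24), TFF1 (-0.99 ± 0.21) and MKI67 (-2.00 ± 0.65, 0.0461). ATF3 (2.13 ± 0.43), HMOX1 (1.52 ± 0.37), BAG3 (1.26 ± 0.41, 0.0497), SQSTM1 (1.24 ± 0.25), MYC (1.10 ± 0.31), PSMD12 (0.83 ± 0.18) and PSMB5 (0.60 ± 0.18) were higher at 24 h. The changes of HSPA1A (0.27 ± 0.27, adjusted p = 0.5), DNAJB1 (1.00 ± 0.36, 0.0681), DDIT3 (0.53 ± 0.32, 0.268), CDKN1A (-0.042 ± 0.23, 0.917, and 0.064 or 0.081 with median or no scaling) and PGR (0.50 ± 0.39, 0.389) between the times did not pass.

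In this comparison 2759 genes were higher and 3331 lower at 24 h, so that 45.3% of the called genes were higher. With median scaling the split was 3593 higher and 2765 lower, 56.5% higher. Requiring at least 2-fold left 3594 genes and an adjusted p under 0.01 left 3074. With slide as a fixed block 3869 genes passed. With 1 array against 2, 3638 passed within slide 2, and within slide 3 limma called 0, with 2407 at an unadjusted p under 0.05. Of the 22 genes named for this comparison that passed, 17 kept their call whichever array was left out. BAG3 lost it without any DMSO array, 4 h array 1 or 3, or 24 h array 2 or 3 (adjusted p 0.0664 to 0.149). MKI67 lost it without DMSO array 1 or 2, 4 h array 1 or 2, or any 24 h array (0.0501 to 0.135), as did MYC without 4 h array 1 or 24 h array 1 or 2 (0.0685 to 0.0722). PSMB5 lost it without DMSO array 2 or 3, any 4 h array, or 24 h array 1 or 3 (0.0506 to 0.0787), and HMOX1 without 4 h array 1 (0.0584).

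Of the 25 lists, 16 differed between the times. From 4 h to 24 h, proteasome subunits rose at 21 of 33 members (26 adjusted over the list alone; median 0.78, camera adjusted p = 1.1e-09, estimated-correlation adjusted p = 0.378). NRF2 targets rose at 16 of 24 (17; median 1.04, camera adjusted p = 1.14e-08, estimated-correlation adjusted p = 0.232), and endoplasmic reticulum genes at 13 of 25 (14; median 0.71, camera adjusted p = 5.63e-05, estimated-correlation adjusted p = 0.378), while XBP1 fell (-1.19). Heat shock genes rose at 7 of 27 (1 adjusted over the list alone; median 0.76, camera adjusted p = 5.63e-05, estimated-correlation adjusted p = 0.56). Without 4 h array 3 that median was 0.35 (camera adjusted p = 0.00932), since the list means were 1.98, 2.03 and 0.77 on the 4 h arrays and 2.11, 2.48 and 2.84 on the 24 h arrays. AP-1 genes rose at 8 of 23 (11; median 0.77, camera adjusted p = 7.92e-05, estimated-correlation adjusted p = 0.258) and ubiquitin and autophagy genes at 7 of 25 (7; median 0.25, camera adjusted p = 0.00475, estimated-correlation adjusted p = 0.408). Estrogen receptor targets fell at 16 of 27 (16 adjusted over the list alone; median -1.09, camera adjusted p = 0.00014, estimated-correlation adjusted p = 0.11), with AREG (4.23) and CTSD (1.14) rising. G1/S genes fell at 21 of 39 (23 adjusted over the list alone; median -1.41, camera adjusted p = 7.32e-08, estimated-correlation adjusted p = 0.474) and G2/M genes at 18 of 34 (23; median -1.96, camera adjusted p = 1.17e-06, estimated-correlation adjusted p = 0.56). NF-kappaB targets rose at 5 of 20 (7 adjusted over the list alone; median 0.32, camera adjusted p = 0.012, estimated-correlation adjusted p = 0.474). They were CXCL8, IL6, RELB, NFKB2 and TNIP1, and BCL3 fell (-1.18). Basal markers LAMC2, ITGA6 (2.51) and EGFR (1.39) rose (median 1.29, camera adjusted p = 0.0265, estimated-correlation adjusted p = 0.258). Without 4 h array 1 the medians of NF-kappaB targets and basal markers were 0.18 and 0.82.

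Shifts between the times were also called in the lists of p53 targets (median -0.28, camera adjusted p = 0.0493, estimated-correlation adjusted p = 0.662) and metallothioneins (median -0.47, camera adjusted p = 0.0406, estimated-correlation adjusted p = 0.599). So were histones (median -0.68, camera adjusted p = 0.0309, estimated-correlation adjusted p = 0.599), ribosomal proteins (median -0.23, camera adjusted p = 0.0406, estimated-correlation adjusted p = 0.711) and RNA polymerase II genes (median 0.31, camera adjusted p = 0.0236, estimated-correlation adjusted p = 0.474). In the p53 list TP53INP1 (-1.96), DDB2 (-1.64), SESN1 (-1.25), CCNG1 (-1.08) and PPM1D (-1.05) fell from 4 h to 24 h. PLK3 rose (0.76). MT1F fell (-1.74), the histone genes H2BC5 (-1.73), H2AZ2 (-1.34), H1-2 (-1.20), H3-3A (-1.11) and H2AZ1 (-0.92) fell. POLR2C (1.02), CTR9 (0.67) and SUPT6H (0.67) rose. No ribosomal protein gene passed limma's adjusted test, and 2 of 46 were lower at an unadjusted p under 0.05. The integrated stress response list did not pass (median -0.15, camera adjusted p = 0.976), and members moved both ways. ATF3, PPP1R15A (1.97) and CTH (1.21) rose, and JDP2 (-2.00), PSAT1 (-1.66), STC2 (-1.29), CHAC1 (-1.25) and PSPH (-0.88) fell. The luminal list had a median of -0.25 (0.11) with 8 members lower and FOXA1, AR and CLDN4 higher. Several of these calls depended on single arrays. The call of p53 targets was lost without DMSO array 1, 2 or 3 (camera adjusted p = 0.0512, 0.0506 and 0.0569), 4 h array 2 or 3 (0.110 and 0.0568) or 24 h array 1 or 2 (0.229 and 0.0730). That of metallothioneins was lost without 4 h array 2 or 3 (0.0699 and 0.165) or 24 h array 2 or 3 (0.0777 and 0.152). That of ribosomal proteins was lost without 4 h array 3 (0.578) or 24 h array 3 (0.208). That of histones was lost without 4 h array 3 (0.0763) or 24 h array 1 or 2 (0.0511 and 0.158). That of RNA polymerase II genes was lost without 4 h array 3 (0.0676) or 24 h array 3 (0.0593), and that of basal markers without 24 h array 1 (0.0652). Medians without single arrays were -0.16 and -0.45 for p53 targets (24 h array 1 or 3), -0.75 and -0.29 for metallothioneins (4 h array 1 or 3) and 0.21 for RNA polymerase II genes (24 h array 3). They were -0.37, -0.30 and -1.04 for histones (4 h array 3, 24 h array 2 or 3) and -0.082 and -0.15 for ribosomal proteins (4 h array 3, 24 h array 3). Other settings also ended the calls of p53 targets (0.0502 to 0.0693), metallothioneins (0.0502 to 0.0653), ribosomal proteins (0.0505 to 0.169), RNA polymerase II genes (0.0838 with quantile scaling) and NF-kappaB targets (0.0993 with probes above background on all 9 arrays). Medians on slide 2, on slide 3 and with slide as a block were 0.68, 0.78 and 0.78 for proteasome subunits, 0.79, 1.23 and 1.00 for NRF2 targets, 0.74, 0.55 and 0.71 for endoplasmic reticulum genes. They were 1.08, 0.33 and 0.75 for heat shock genes, 0.63, 0.64 and 0.79 for AP-1 genes and 0.21, 0.44 and 0.29 for ubiquitin and autophagy genes. The others were -1.20, -0.85 and -1.17 for receptor targets, -1.09, -1.65 and -1.41 for G1/S, -1.60, -2.60 and -1.91 for G2/M, 0.24, 0.42 and 0.20 for NF-kappaB targets and 0.99, 1.29 and 1.13 for basal markers. For p53 targets, metallothioneins, histones, ribosomal proteins and RNA polymerase II genes they were -0.35, -0.39 and -0.32, then -0.54, -0.53 and -0.45, then -1.36, -0.11 and -0.79, then -0.23, -0.12 and -0.23, and 0.19, 0.24 and 0.28. All 16 lists had the same sign on both slides. With an estimated correlation, camera called 0 of 25, with 4 at an unadjusted p under 0.05.

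**Figure D3:**
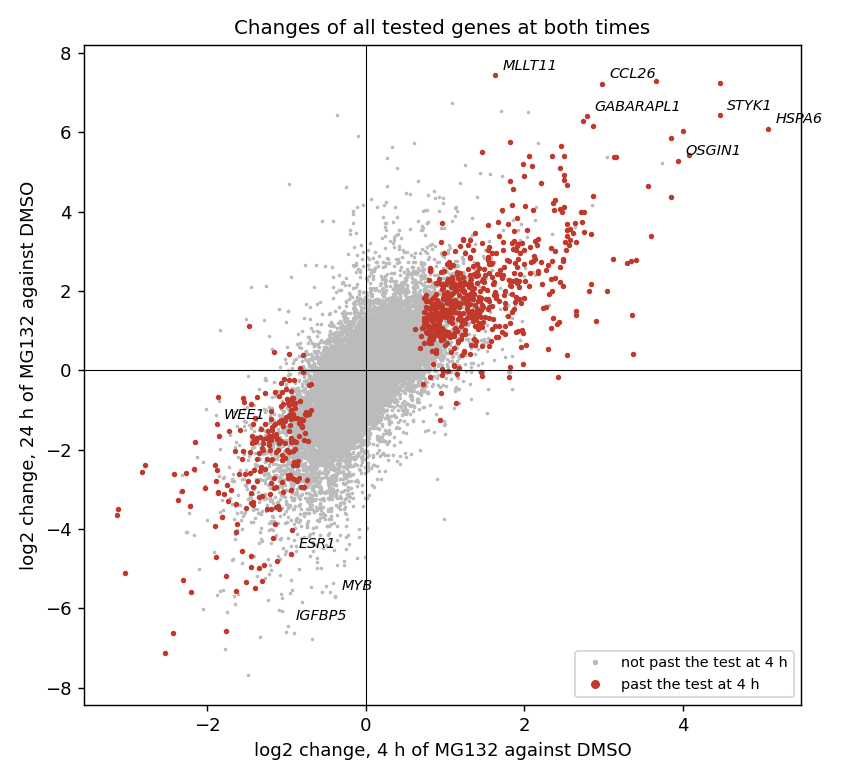
Log2 change at 24 h (vertical axis) against log2 change at 4 h (horizontal axis), both relative to the same 3 DMSO arrays, for the 22655 genes tested; red points passed the test at 4 h. OSGIN1 rose at both times (3.94 and 5.28), and ESR1 fell at both (-0.94 and -4.62).

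Of the 788 genes called at 4 h, 92.3% were called at 24 h in the same direction, 520 higher and 207 lower at both times, and 4 were called in opposite directions. Of these 4, ARHGEF40, GLS2 and TP53INP1 were higher at 4 h and lower at 24 h, and 1 transcript without a symbol did the reverse. Independent lists of these lengths would share 112 higher and 51.2 lower genes. Over all genes the changes at the 2 times had a correlation of 0.713 across genes, which are not independent replicates, and 75.1% had the same sign. Because both times use the same DMSO group, data simulated without change gave a correlation of 0.499 and 66.7% of equal signs. The DMSO values were simulated too, so these figures do not measure what the real DMSO arrays contribute. In 50 simulations the highest overlap of limma calls was 0. Since no change was simulated, an overlap near 0 was set in advance, and it does not test the observed overlap. The covariance was 0.439 against 0.0569 simulated, a difference of 0.383. The 3 DMSO arrays are too few to be split, so part of the excess may come from the shared controls. Of the genes that rose at 4 h, such as HMOX1 and SQSTM1, 234 were higher still at 24 h, 41 were lower at 24 h than at 4 h, and 285, such as HSPA1A and CDKN1A, had no call between the times. Of the genes that fell at 4 h, ESR1 among them, 109 were lower still at 24 h, 13 were higher at 24 h than at 4 h, and 106 had no call between the times. The number shared in direction was 69 with slide as a fixed block, 154, 179 and 342 without DMSO array 1, 2 or 3. It was 172 and 223 without 4 h array 1 or 2, and 1192 without 24 h array 3.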

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

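The tests of the G2/M pattern, of a weaker exposure of a 4 h sample and of compressed signal on its array were chosen after the values they bear on were seen; the other tests of this part were chosen before.

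Cells given MG132 for 24 h differed from those given it for 4 h by a test of the difference itself for 6090 genes. The labels name no vehicle samples of their own for either time, so longer culture was not separated from longer exposure to MG132. By camera, the lists that differed were those of proteasome subunits (0.78), heat shock genes (0.76, or 0.35 without 4 h array 3), endoplasmic reticulum genes (0.71), NRF2 targets (1.04), metallothioneins (-0.47), AP-1 genes (0.77), ubiquitin and autophagy genes (0.25) and estrogen receptor targets (-1.09), as median log2 differences of 24 h from 4 h. The others were G1/S (-1.41), G2/M (-1.96), p53 targets (-0.28), NF-kappaB targets (0.32), RNA polymerase II genes (0.31), histones (-0.68), ribosomal proteins (-0.23) and basal markers (1.29). With an estimated correlation camera called 0 of these lists (lowest adjusted p = 0.110), with 4 at an unadjusted p under 0.05. The calls of p53 targets, metallothioneins, histones, ribosomal proteins, RNA polymerase II genes and basal markers were each lost without at least 1 of the arrays (highest camera adjusted p = 0.229, 0.165, 0.158, 0.578, 0.0676 and 0.0652). Of the named genes, MMP1 (6.01), MLLT11 (5.81), NIBAN1 (5.13), LAMC2 (4.70), F2RL1 (4.31), ATF3 (2.13), HMOX1 (1.52), BAG3 (1.26), SQSTM1 (1.24), MYC (1.10), PSMD12 (0.83) and PSMB5 (0.60) were higher at 24 h. IGFBP5 (-5.46), MYB (-5.29), SCUBE2 (-5.03), PCLAF (-4.69), ELAPOR1 (-4.54), ESR1 (-3.68), GREB1 (-3.22), MKI67 (-2.00), CCND1 (-1.09) and TFF1 (-0.99) were lower.

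Genes of G2/M and mitosis at 4 h had a median of -1.90 against DMSO on slide 2 and 1.05 on slide 3, each with 1 DMSO array. The tables argue against the slide itself, since the group-centred list means of DMSO and 4 h arrays on slide 2 alone spanned 1.74 on the log2 scale, and all 34 members were lower on 4 h array 3 than on 4 h array 1 of that slide. A state shared by the samples numbered 3, such as a slower proliferation of that experiment, is a candidate explanation: all 34 members were lower on DMSO array 3 than on the other DMSO arrays, and the within-number differences had an SD of 0.187 against 0.88 among the 4 h arrays. An effect of MG132 in addition to that state also goes with the tables: the 3 within-number differences were -0.98, -0.88 and -0.62, with a mean of -0.82 that is 4.41 times their SD. It would not by itself turn the sign between the slides, each pair lies on 2 slides, and the pairing was found in the same data, so both remain hypotheses.

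Heat shock genes rose by 1.98 and 2.03 on 4 h arrays 1 and 2 but by 0.77 on 4 h array 3, a ratio of 0.385 (0.451 within replicate numbers). The tables argue against compressed signal on that array: the slope of its spike-in controls was 0.934 against 0.957 and 0.948 on 4 h arrays 1 and 2, a ratio of 0.980 to their mean. A weaker exposure of that sample would lower the other stress lists too; their median ratio was 1.06, and 0.824 within replicate numbers (proteasome subunits 0.963, NRF2 targets 0.835, p53 targets 0.814, integrated stress response 0.599). It stays open, since over 1927 genes with large changes at 24 h (heat shock genes left out) that array had a slope of 0.645 on the mean of the other 4 h arrays. Arrays 1 and 2 had slopes of 0.997 and 1.02, each on a mean that includes array 3, so they are not a like comparison. Changes were taken from the mean of all DMSO arrays, and no slope within replicate numbers was computed. No biological explanation was tested, because the design names none for a single sample.

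At 24 h, 90 genes were at least 16-fold higher than in DMSO, 73 of them with a symbol (MLLT11, CCL26 and STYK1 among them), and 133 were at least 16-fold lower. The 6191 probes above background on no array had a median change of 0.068 at 24 h. They were picked for staying near background on the 24 h arrays too, so they test higher background there only weakly. Scaling is argued against by the 87, 96 and 90 such genes under quantile, median and no scaling. Signal near background in DMSO stays open as a source of inflated sizes, since 57.8% of these genes were well above background on all 3 DMSO arrays and with normexp background correction 29 of the 90 were still at this size, although its offset shrinks folds of dim genes by construction. The design names the treatment as the biological explanation. It was not separated from signal near background in DMSO, nor fully from higher background at 24 h.

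With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. All splits but the real one mix arrays of both groups, so a real difference widens their spread. Few or no limma calls in them follow by construction and do not test the real count. At 4 h the real split gave 788 genes and limma called 0 in the highest of the others, with up to 1241 at an unadjusted p under 0.05. Only the real split reached its count. At 24 h the real split gave 9613 and the highest other 0 (up to 1017 unadjusted), and between the times 6090 and 0 (up to 1800 unadjusted), again with only the real split reaching its count. For gene lists, the real split called 12 at 4 h, 15 at 24 h and 16 between the times, and the highest others 12, 13 and 12. Counting the real split itself, 3 splits at 4 h, and 1 in each of the other comparisons, reached the real number. Among the 4 h splits that part all 3 numbered pairs, limma called 0 genes in each of the others (58 to 528 unadjusted, against 4120 for the real split), and they called at most 10 lists.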

How the results depend on the processing

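The tests with the replicate block and only DMSO and 4 h arrays, without replicate 3 of DMSO and of 4 h together, and without arrays of the group outside a comparison were chosen after the data were seen, and the others before. With the authors' value table every count was the same, since it holds the same values.

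At 4 h (788 genes), normexp, quantile scaling, median scaling, the filter on all 9 arrays, slide as a random block and trend with robust gave 993, 818, 834, 859, 672 and 1058. Every probe on its own gave 1065, a count of probes. Counts that moved by over 1.5 times were 409 with no scaling (the all-gene median then being -0.13), 435 with no filter, 70 with slide as a fixed block, 1500 with only the 2 groups, 4046 with array weights, 177 at an adjusted p under 0.01, and 258 without replicate 3 of DMSO and 4 h together. At 24 h (9613) the planned settings gave 8326 to 11077 genes, or 12943 probes with every probe on its own. The exceptions were 6906 with slide as a fixed block, 4980 within slide 2, 6458 at an adjusted p under 0.01 and 6142 at 2-fold. Between the times (6090) the planned settings gave 4175 to 6638 genes, or 8235 probes with every probe on its own. Exceptions here were 3869 with slide as a fixed block, 3638 within slide 2, 3074 at an adjusted p under 0.01 and 3594 at 2-fold. Within slide 3 limma called 0 genes in each comparison (855, 4318 and 2407 unadjusted). Slides 2 and 3 hold 4 arrays each with 1 DMSO array, and the spread within each comes from a single pair of arrays, so counts within these slides carry little weight. The genes shared at both times (727) were 69 with slide as a fixed block. Leaving out 1 array gave 160 to 1342 genes at 4 h, 7658 to 9913 at 24 h, 4361 to 6260 between the times and 154 to 1192 shared. Stricter thresholds lower a count by construction. Slide as a fixed block takes DMSO array 1 out of every contrast. Without that array alone, 160 genes were called at 4 h and 154 were shared. What else lowered the counts of the slide block was not tested, nor was the cause for the other settings.

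The replicate block, whose numbers pair DMSO with 4 h samples, gave 861 genes at 4 h, or 2210 (1150 higher, 1060 lower) with only those 6 arrays. Besides the calls given with the 4 h results, it ended those of MT2A and MT1G at 24 h (adjusted p = 0.0504 and 0.0597). Between the times it ended those of BAG3 (0.0752) and of metallothioneins, p53 targets and ribosomal proteins (camera adjusted p = 0.0564, 0.0505 and 0.0505), and DNAJB1 passed (0.0402). It changed no other call among the 25 lists and the named genes, while of all genes called here it shared 669 of 788 at 4 h, 9355 of 9613 at 24 h and 5801 of 6090 between the times. It gave 10085 genes at 24 h, 6638 between the times and 792 shared. Between DMSO and 24 h the same-numbered pairs correlated at -0.082, 0.170 and 0.109 (highest other 0.114), and between 4 h and 24 h at -0.0080, -0.073 and 0.132 (highest other 0.149), so these share only a number.

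Of the 25 lists, camera called 12 at 4 h, 15 at 24 h and 16 between the times, and 0, 0 and 0 with an estimated correlation (6, 5 and 4 unadjusted). Other settings gave 11 to 18, and leaving out 1 array 12 to 15, 14 to 16 and 11 to 16. Counting each list under each setting as a value, 1470 of 1575 kept their side of the threshold, 82 lost the call and 23 gained one. For named genes, 3863 of 4304 kept it, 425 lost it and 16 gained it. These totals include the authors' value table, which could not move a value. They also pool the comparisons, and called with uncalled results, so they do not describe the 4 h calls. No value called in either setting turned its sign, while 69 values called in neither did, from 15 list medians and 9 gene changes. These counts leave out list medians within single slides. Of the lists called at 4 h, G1/S and G2/M had medians of 0.31 and 1.05 on slide 3, against -0.60 and -0.82 over all arrays. Metallothioneins at 4 h were among the lists gained in other settings (camera adjusted p = 0.0147 with normexp, 0.0288 with no scaling).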

Other observations

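The 5 gene lists of this part other than zinc finger genes, and the zinc finger test, were chosen after the genes with the largest changes were seen; the test of neighbouring genes was chosen before its result was seen.

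Growth factor genes of the ERBB receptor family rose at 24 h: 7 of 9 tested rose (median 2.33, camera adjusted p = 0.000532, estimated-correlation adjusted p = 0.235). The median was 1.54 with the 4 members below background in DMSO at their bound. HBEGF rose by 4.43 ± 0.37, BTC by 2.33 ± 0.20 and AREG, also among the estrogen receptor targets, by 4.12 ± 0.39. EGF was at least 23.2-fold, TGFA at least 2.9-fold, EREG at least 2.39-fold and NRG1 at least 1.7-fold higher. Feedback and target genes of the MAPK pathway rose at 12 of 16 (median 1.62, camera adjusted p = 0.000532, estimated-correlation adjusted p = 0.257). ETV5 (4.65 ± 0.77, above background on 1 of 3 DMSO arrays), PHLDA1 (4.11 ± 0.48) and EPHA2 (2.31 ± 0.26) rose, SPRY4 was at least 8.49-fold higher and CCND1 fell. At 4 h that list did not pass (median 0.18, camera adjusted p = 0.803). Because these lists and those of the next paragraph were picked after changed members were seen, their p-values restate that choice and do not test whether the sets move, and with an estimated correlation none passed.

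Subunits of the lysosomal membrane proton pump rose at 10 and fell at 3 of 19 at 24 h (median 0.58, camera adjusted p = 0.01, estimated-correlation adjusted p = 0.257). ATP6V1A rose by 1.72 ± 0.17, and ATP6V0D2 was at least 16.1-fold higher, while ATP6V0A4 (-5.74 ± 0.58, above background on 2 of 3 treated arrays), ATP6V1C2 (-2.35 ± 0.27) and ATP6V1B1 (-1.35 ± 0.19) fell. Genes known from neurons rose at 8 and fell at 2 of 21 (median 0.41, camera adjusted p = 0.00785, estimated-correlation adjusted p = 0.235). MAP1B rose by 5.16 ± 0.29 and KIF5A was at least 27.2-fold higher, while STMN3 (-3.28 ± 0.35) and SYT1 (-1.27 ± 0.23) fell. UCHL1 belongs to this list and to that of ubiquitin genes. At 4 h 4 members rose, UCHL1, MAP1B, KIF5A and MLLT11 (camera adjusted p = 0.00386, estimated-correlation adjusted p = 0.276). Germline and cancer-testis genes did not move as a list at 24 h (median 0.16, camera adjusted p = 0.692, estimated-correlation adjusted p = 0.847), with 1 of 14 past the test, STK31, lower by at least 1.53-fold and below background on the 24 h arrays. Between 24 h and DMSO, 171 genes were well above background on all treated arrays and no DMSO array and 288 the other way round, against 82 and 32 at 4 h.

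The hypothesis that short-lived regulators fall first was tested on the 383 genes with ZNF symbols, at 4 h. Their median change was 0.0062 (camera adjusted p = 0.803 over the lists of this part), so these genes did not fall as a set at 4 h. No half-lives were measured, so the hypothesis stays open for short-lived regulators. At 4 h 16 of the ZNF genes were higher and 2, ZNF362 and ZNF367, were lower, and at 24 h 58 were higher and 88 lower. Of all genes tested, 3.48% were called at 4 h and 42.4% at 24 h. The hypothesis that adjacent genes move together was tested on 13238 adjacent pairs among 14116 genes. Their changes at 24 h correlated at 0.0736 across genes, which are not independent. This lay above the highest of 10000 permuted orders (0.0336, permutation p = 1e-04, the smallest they can give). At 4 h the correlation was 0.0777. The size of this correlation is small, and pairs whose symbols share their first 3 letters had been left out. A value of 0.0736 does not tell shared regulation from other sources such as overlapping transcripts.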
